A study of Homo sapiens with 4 samples.

How the data were processed

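Chromatin immunoprecipitation with sequencing (ChIP-seq) had been carried out in primary human epidermal keratinocytes that were differentiated for 3 days by confluence and calcium, per the labels' protocols. An antibody against 1 of 4 proteins was used in each sample: ZNF750, KLF4, RCOR1 or LSD1. One peak list per antibody was analysed, so there were no replicates, and no input library or unrelated antibody was used here. Reads had been aligned with Bowtie to the human build hg19, per the submitters' processing notes. The peaks carry names in the style of MACS, per the entries of the lists. The version and settings of the peak caller, its control library, the number of reads and whether libraries were pooled before calling are not given in the sources used here.

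Each deposited list gives the chromosome, start, end, name and score of every peak. The score is the authors' own peak score, and its scale is not stated. The lowest score is 60.01, 60.01, 60.01 and 60.0 in the ZNF750, KLF4, RCOR1 and LSD1 lists, so a minimum of about that size had been applied before deposit. The running numbers in the peak names reach 44719, 38831, 50837 and 20936, and the lists hold 48.9%, 46.5%, 29.1% and 53.3% as many peaks, so the authors deposited subsets of longer lists. The rule that chose these subsets is not stated. Scores were used to rank or select peaks within a list, to give medians of ZNF750 scores by partner class and to correlate the scores of overlapping peaks. They were not compared in size between lists. Because the read depth is unknown, differences in list length cannot be separated from differences in depth or antibody quality.

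Positions are given from 1 on hg19. Peaks of 2 lists were counted as shared when they overlapped by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and neighbouring peaks are not independent. As a reference for each of the 6 pairs, the second list was moved by a random distance along each chromosome, wrapping at its end, 1000 times. The one-sided permutation p from these shifts cannot go below 0.001. It describes the lists at hand and says nothing about replicate cultures. Shares of the same ZNF750 peaks with different partners were compared by an exact McNemar test (two-sided). Association between partners at ZNF750 peaks was tested by Fisher's exact test (two-sided), and odds ratios carry Wald 95% intervals. Both were adjusted by Benjamini-Hochberg over 3 comparisons. Sharing by score was compared between the highest and the lowest quintile of each list by Fisher's exact test (two-sided, adjusted over 12 comparisons). Score correlations were tested with 100000 permutations and are across peaks, which are not independent replicates. Peak midpoints were counted in 1 Mb windows of the 22 autosomes and in hg19 cytogenetic bands taken from the band table of the R package circlize. Densities carry exact Poisson 95% intervals. Peaks on the sex chromosomes were kept in the overlap counts and left out of windows and bands.

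The designs and a first set of alternatives were fixed before the data were examined. The following were added after the data were seen: the exact McNemar tests, the tests between the highest and lowest quintile, the permutation tests of score correlations, the random placement of peaks in windows, the correlation of window counts, the count of merged regions, the strata of score and width, the comparison at RCOR1 peaks, the local shift, the settings without centromere-near and repeat-like peaks or without sex chromosomes, and all counts in bands. So were the ranking by quintiles of peak width, the width quintiles and lowest-quintile shifts at RCOR1 peaks, and the count of shared peaks near centromeres. Named peaks were the 5 highest-scoring ZNF750 peaks in each of 3 sets (overlapping all 3 partners, KLF4 alone, and RCOR1 and LSD1 without KLF4) and the 5 windows of 1 Mb with the most ZNF750 peaks. The other results designed in advance needed gene positions or sequence on hg19. These were the distance of peaks to transcription starts, the tests of fixed gene lists near peaks, the comparison of differentiation with progenitor genes, and the motif search. The only gene table at hand is on GRCh38, positions were not converted between builds, and these results and their alternatives were not run. No peak is therefore assigned to a gene. Loci are named only through the cytogenetic band in which textbooks place them, and a band holds many other genes.

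The overlap counts and shifts were tested on simulated data with the widths of the ZNF750 and KLF4 peaks. Of 5000 planted shared peaks among 21710 simulated ZNF750 peaks, 4887.6 were recovered after subtracting the mean of the shifts, and 1959.6 of 2000 were recovered in a second simulation. Of 100 unrelated pairs of shorter simulated lists, tested with fewer shifts, 2 passed a threshold of 0.05. All simulated peaks were placed evenly at random along the chromosomes. The deposited lists cluster in the same regions, so this rate does not show how the shifts behave for unrelated lists that cluster together. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.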

Results

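Binding sites of ZNF750 and of 3 proteins named as its partners were mapped in differentiated human keratinocytes. ZNF750 is a zinc finger protein that promotes terminal differentiation of the epidermis, and KLF4 is a transcription factor needed for the skin barrier. LSD1 (gene symbol KDM1A) is a histone demethylase, and RCOR1, also called CoREST, is the scaffold that joins LSD1 to chromatin. The lists held 21862 ZNF750 peaks, 18051 KLF4 peaks, 14803 RCOR1 peaks and 11154 LSD1 peaks. Median peak widths were 930 bp for ZNF750, 680 bp for KLF4, 912 bp for RCOR1 and 725 bp for LSD1, and the peaks covered 22.4, 13.8, 14.9 and 8.38 Mb. Merged together, the peaks formed 49942 separate regions. Of these, 38094 (76.3%) held peaks of a single protein, 8610 held peaks of 2 proteins, 2433 held peaks of 3, and 805 (1.61%) held peaks of all 4. Each antibody was represented by 1 list, so no difference below could be set against the spread between replicates.

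The first question was how often ZNF750 and its partners lay at the same sites. KLF4 peaks overlapped 5269 of the 21862 ZNF750 peaks (24.1%, 95% interval 23.54 to 24.67). LSD1 peaks overlapped 3083 (14.1%, 13.64 to 14.57) and RCOR1 peaks 2674 (12.23%, 11.8 to 12.67). Seen from the partners, 29.29% of KLF4 peaks, 27.67% of LSD1 peaks and 18.05% of RCOR1 peaks overlapped a ZNF750 peak. After random shifts along the chromosomes, a mean of 242.0 ZNF750 peaks met a KLF4 peak, 147.5 met an LSD1 peak and 227.2 met an RCOR1 peak. The observed sharing was 21.8 times these values for KLF4, 20.9 times for LSD1 and 11.8 times for RCOR1. KLF4 shared more ZNF750 peaks than RCOR1 did (exact McNemar test, chosen after the data were seen, adjusted p = 1.39e-290) and more than LSD1 did (adjusted p = 4.95e-200, exact). When the 11154 highest-scoring peaks of each list were used, KLF4 still overlapped the largest share of ZNF750 peaks, 22.16%, against 17.6% for LSD1 and 14.12% for RCOR1. The smaller difference between LSD1 and RCOR1 (adjusted exact p = 4.97e-14) was kept in 3 of 5 alternatives, with midpoints within 200 bp, with equal list lengths and without centromere-near and repeat-like peaks (a setting chosen after the data were seen). It was lost with a reciprocal overlap of 50% (2472 against 2404 ZNF750 peaks, adjusted exact p = 0.1941), and its direction turned among the upper 50% of each list by score (11.03% against 11.59%, adjusted exact p = 0.0936).

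RCOR1 and LSD1 shared the most relative to chance of the 6 pairs. LSD1 overlapped 4042 of 14803 RCOR1 peaks (27.31%, 26.59 to 28.03), and RCOR1 overlapped 36.27% of LSD1 peaks, 39.2 times the shifted mean of 103.2. KLF4 with LSD1 followed at 27.7 times, with 2958 of 18051 KLF4 peaks (16.39%). KLF4 with RCOR1 stood at 15.3 times, with 2616 peaks (14.49%). In none of the 6 pairs did any of the 1000 shifts reach the observed count (one-sided permutation p = 0.001, the smallest these shifts can give). Moving each peak by only 10 to 50 kb, a setting chosen after the data were seen, keeps the regional density of peaks and raised the chance level. The ratios then lay between 7.56 for ZNF750 with RCOR1 and 21.1 for RCOR1 with LSD1.

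**Figure D1:**
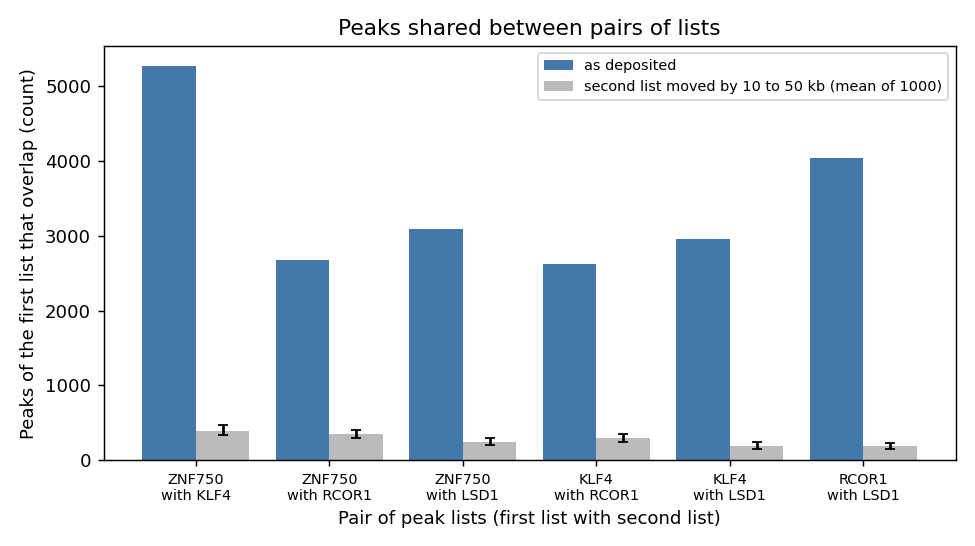
Number of peaks of the first list that overlap a peak of the second by at least 1 bp (blue), for each of the 6 pairs, and the mean after moving the second list by 10 to 50 kb (grey, with the lowest and highest of 1000 draws as error bars). The observed counts range from 2616 for KLF4 with RCOR1 to 5269 for ZNF750 with KLF4, and the means of the moved lists from 191.3 to 395.5.

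The next question was whether KLF4 and the chromatin regulators RCOR1 and LSD1 lay at the same or at different ZNF750 peaks. Of the ZNF750 peaks, 14260 (65.23%) overlapped no partner and 7602 (34.77%, 34.14 to 35.41) overlapped at least 1. KLF4 alone lay at 3252 ZNF750 peaks (14.88%), RCOR1 or LSD1 without KLF4 at 2333 (10.67%), and KLF4 together with RCOR1 or LSD1 at 2017 (9.23%). All 3 partners lay at 791 (3.62%, 3.37 to 3.87). KLF4 without the regulators and the regulators without KLF4 each accounted for more ZNF750 peaks than KLF4 together with a regulator. This order was not examined under the alternative settings and does not show that the partners avoid each other. The deposited lists are subsets of longer ones, so a ZNF750 peak with no overlap may still meet a partner peak that was left out.

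The partners met at the same ZNF750 peaks more often than independence would give. RCOR1 overlapped 25.2% of the ZNF750 peaks that carried KLF4 and 8.11% of those that did not, an odds ratio of 3.82 (3.51 to 4.15, Fisher's exact test, adjusted p = 4.27e-209). LSD1 overlapped 28.09% of the ZNF750 peaks with KLF4 and 9.66% of those without, an odds ratio of 3.65 (3.37 to 3.95, adjusted p = 2.90e-217, Fisher's exact test). The tie between the 2 chromatin regulators was the closest. LSD1 overlapped 52.62% of the ZNF750 peaks with RCOR1 and 8.73% of those without, an odds ratio of 11.6 (10.6 to 12.7). ZNF750 peaks with all 3 partners had a median score of 258.9, those with KLF4 alone 210.9, and those with no partner 159.2. Within 25 strata of ZNF750 score and width, also chosen after the data were seen, the odds ratios were 3.43, 3.2 and 10.4.

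**Figure D2:**
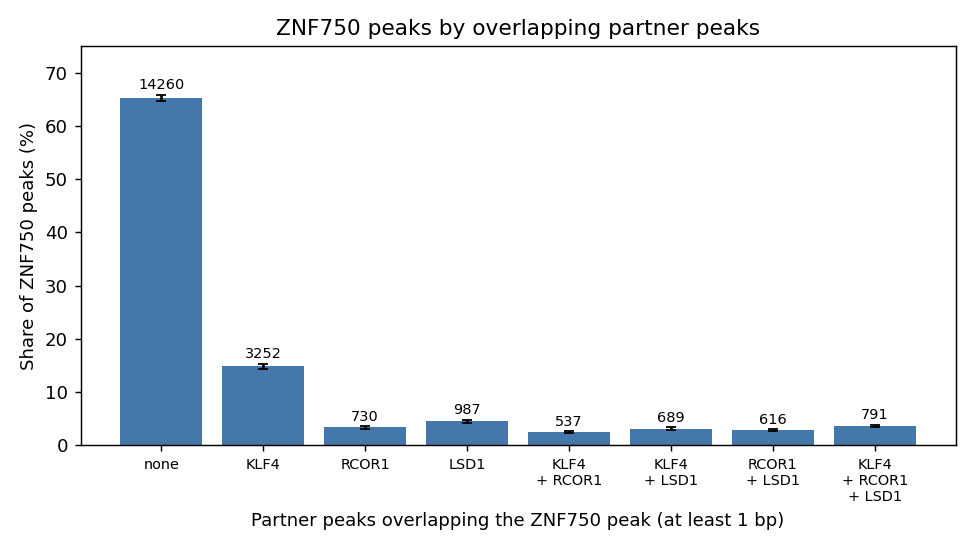
Share of the 21862 ZNF750 peaks (%) by the combination of partner peaks that overlap them, with exact 95% intervals as error bars and the number of peaks above each bar. Peaks with no partner make up 65.23%, those with KLF4 alone 14.88% and those with all 3 partners 3.62%.

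The pairing of RCOR1 with LSD1 was also examined at RCOR1 peaks, a comparison chosen after the data were seen. LSD1 overlapped 1430 of the 2672 RCOR1 peaks that met ZNF750 (53.52%, 51.61 to 55.42) and 2612 of the 12131 that did not (21.53%, 20.8 to 22.27), an odds ratio of 4.2 (3.84 to 4.58). For KLF4 the shares were 52.86% with and 21.84% without, an odds ratio of 4.01 (3.67 to 4.38). Within 25 strata of RCOR1 peak score and width the odds ratios were 2.67 (2.42 to 2.94) for ZNF750 and 2.15 (1.95 to 2.36) for KLF4.

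In every list, and for every partner, more of the highest-scoring peaks were shared than of the lowest-scoring. From the lowest to the highest quintile of ZNF750 scores, the share with KLF4 went from 15.25% to 34.35%, with LSD1 from 8.51% to 22.84% and with RCOR1 from 8.51% to 20.38%. In the KLF4 list, the share with ZNF750 went from 19.08% to 40.33%. The steepest rise was that of RCOR1 peaks shared with LSD1, from 4.59% (3.87 to 5.41) to 63.49% (61.73 to 65.23). The reverse relation was shallow: LSD1 peaks were shared with RCOR1 at 29.18% in the lowest and 42.99% in the highest LSD1 quintile. In each of the 12 comparisons the highest quintile exceeded the lowest (Fisher's exact test, largest adjusted p = 8.64e-22). Where peaks did overlap, their scores were only loosely related. Across overlapping pairs of peaks, Spearman's rho was 0.4 (Pearson's r = 0.42) for RCOR1 with LSD1, 0.3 (r = 0.36) for KLF4 with RCOR1, and 0.2 (r = 0.15), 0.19 (r = 0.18) and 0.15 (r = 0.1) for ZNF750 with RCOR1, KLF4 and LSD1. For KLF4 with LSD1 it was 0.18 (r = 0.24). Each of the 6 had an adjusted permutation p of 1e-05, the smallest that 100000 permutations can give. With a reciprocal overlap of 50% the steepest rise was from 4.12% to 45.1%, and the rises in the ZNF750 list were smaller for KLF4 (14.04% to 24.47%) and LSD1 (8.0% to 16.05%).

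**Figure D3:**
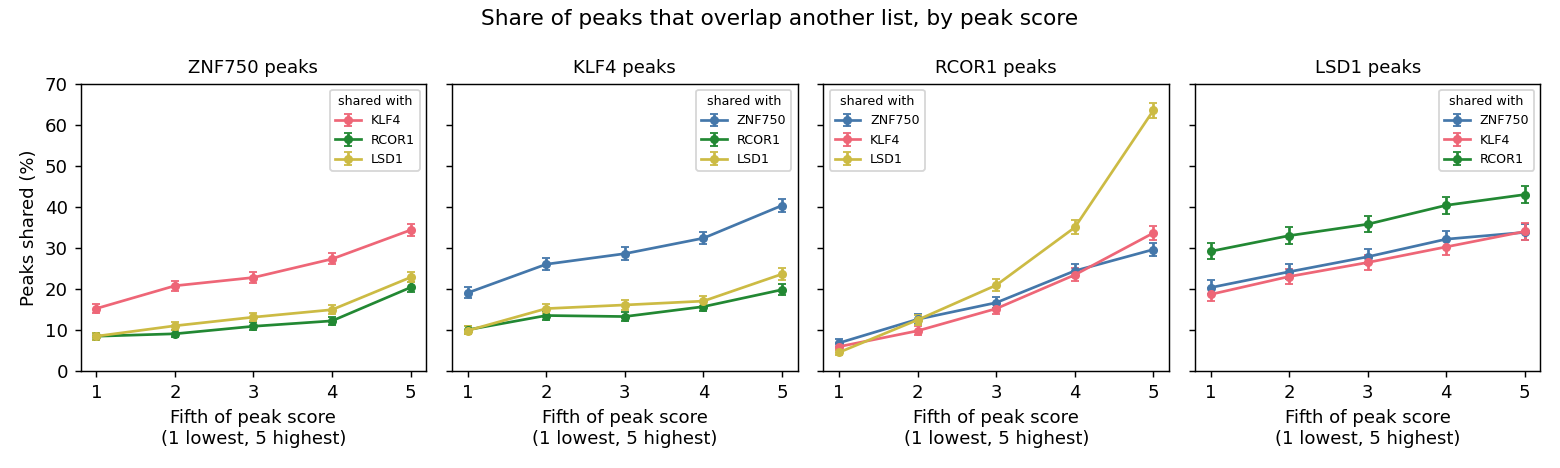
Share of peaks (%) that overlap a peak of another list, by quintile of the authors' peak score within the list (1 lowest, 5 highest), with exact 95% intervals as error bars and 1 panel per list. The RCOR1 panel holds the steepest line, its share with LSD1, which goes from 4.59% to 63.49%.

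The ZNF750 peaks with the highest scores were then located. Among ZNF750 peaks that met all 3 partners, the highest lay on chromosome 21 at 9826892 to 9827969 (band p11.2, score 2926.87). This site ranked 5 in the KLF4 list, 1 in the RCOR1 list and 13 in the LSD1 list, and lies in a variable band beside the centromere. The peak on chromosome 1 at 91852422 to 91853565 (band p22.2, score 2288.34) ranked 1, 2 and 4 in the same lists. The other 3 of the set lay on chromosome 17 at 4063998 to 4065682 (p13.2, score 2708.99), on chromosome 9 at 111773865 to 111775844 (q31.3, 2290.23) and on chromosome 9 at 87061780 to 87063015 (q21.33, 2218.5), with KLF4 ranks of 3038, 7055 and 15233, RCOR1 ranks of 1754, 287 and 4004, and LSD1 ranks of 1780, 2126 and 10999. Among ZNF750 peaks that met KLF4 alone, the highest were on chromosome 3 at 32463343 to 32464318 (p22.3, 1953.91), chromosome 9 at 136738694 to 136740358 (q34.2, 1914.45), chromosome 1 at 45264916 to 45266179 (p34.1, 1865.78), chromosome 1 at 222884491 to 222885703 (q41, 1834.4) and chromosome 6 at 48794254 to 48796016 (p12.3, 1805.86). The KLF4 peak at the last of these ranked 44 in its own list. Among those that met RCOR1 and LSD1 without KLF4, the highest were on chromosome 12 at 15954240 to 15955685 (p12.3, 1856.76), chromosome 6 at 31170574 to 31172392 (p21.33, 1786.43), chromosome 7 at 8329950 to 8331534 (p21.3, 1753.95), chromosome 21 at 35173518 to 35175119 (q22.11, 1736.88) and chromosome 22 at 28711598 to 28712768 (q12.1, 1651.67). The site on chromosome 21 q22.11 had the strongest regulators of this set, with ranks of 965 for RCOR1 and 178 for LSD1. No annotation of hg19 was used here, so the genes at these sites are not named.

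Peaks were unevenly spread along the autosomes. The 289 windows of 1 Mb with the most peaks, of 2897, held 22.0% of ZNF750 peaks, 27.3% of KLF4 peaks, 29.8% of LSD1 peaks and 31.5% of RCOR1 peaks, against 16.9%, 17.6%, 19.9% and 18.4% under random placement (permutation p = 0.001 for each, the smallest possible). No window was left out for unassembled sequence, where peaks cannot fall. ZNF750 peaks were absent from 278 windows (9.6%) and LSD1 peaks from 519 (17.9%). Windows that cannot hold peaks raise the observed shares, so the p-value alone does not show clustering among the other windows. The window with the most ZNF750 peaks was on chromosome 3 from 189000001 to 190000000, in band 3q28, with 29 ZNF750 peaks where the autosomal mean was 7.32. Textbooks place TP63, the gene of the p63 transcription factor that maintains epidermal progenitors, in this band. The window held 15 KLF4, 10 RCOR1 and 7 LSD1 peaks. KLF4 overlapped 7 of its ZNF750 peaks, RCOR1 4 and LSD1 2, and 20 met no partner. Over all ZNF750 peaks, KLF4 overlapped 24.1%, RCOR1 12.23% and LSD1 14.1%, and 65.23% met no partner, so the window was not unusual in its KLF4 sharing or its peaks without a partner. With windows of 500 kb, the part from 189500001 to 190000000 held 16 ZNF750 peaks and shared the first rank with a window on chromosome 18 from 3000001 (band p11.31). The next windows of 1 Mb were chromosome 21 from 36000001 (band q22.12, 23 ZNF750 peaks), and chromosome 1 from 1000001 (p36.33), chromosome 2 from 173000001 (q31.1) and chromosome 15 from 40000001 (q15.1), each with 22. Across the 2897 windows the peak counts of the lists rose and fell together, with Spearman's rho from 0.74 to 0.8 over the 6 pairs. Windows are not independent replicates, and windows where no list can have peaks raise these correlations.

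**Figure D4:**
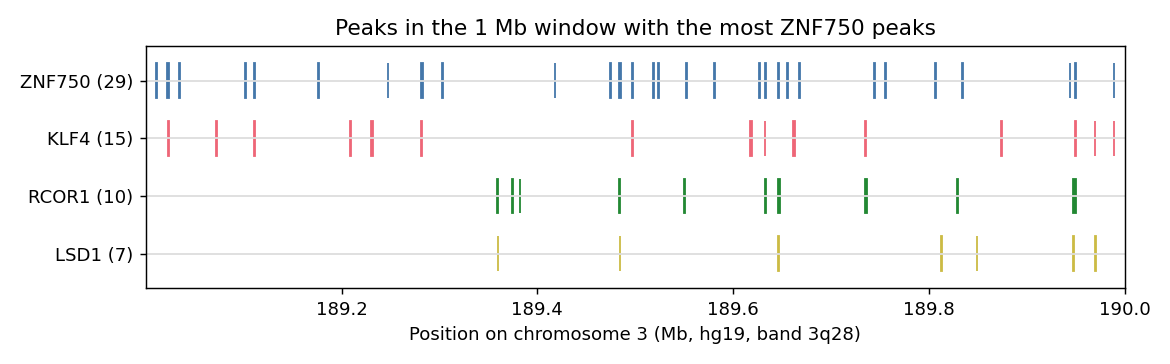
Map of the 1 Mb window with the most ZNF750 peaks, on chromosome 3 from 189000001 to 190000000 (hg19, x axis in Mb), with 1 row per list and each peak drawn to scale. The rows hold 29 ZNF750, 15 KLF4, 10 RCOR1 and 7 LSD1 peaks.

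The lists were also counted in 9 cytogenetic bands that hold known loci by textbook mapping, a set chosen after the data were seen and not tested for enrichment. The autosomal density was taken over the full length of the autosomes, centromere, variable and stalk bands included. Peaks are few in those bands, so all ratios would be somewhat lower without them, and an interval that barely excludes 1 should not be read as raised density. Band 1q21.3, home of the epidermal differentiation complex with the genes of the cornified envelope, held 70 ZNF750 peaks, 2.02 times the autosomal density (Poisson 95% interval 1.58 to 2.56) and above 97.6% of 709 bands. KLF4 was at 2.51 times (1.97 to 3.17), LSD1 at 2.42 times (1.75 to 3.26) and RCOR1 at 1.57 times (1.1 to 2.16). Among the 366 bands of the same stain, 1q21.3 stood above 96.4% for ZNF750, 96.2% for KLF4, 91.5% for LSD1 and 72.7% for RCOR1. Of these 70 ZNF750 peaks, 22 met KLF4 (31.43%, 20.85 to 43.63) and 11 met RCOR1 or LSD1 (15.71%, 8.11 to 26.38). Both intervals include the genome-wide shares of 24.1% and 19.9%. In 12q13.13, with the type II keratins, KLF4 (2.46 times), LSD1 (2.26) and ZNF750 (1.84, 1.35 to 2.45) were dense, while RCOR1 was at 1.05 times (0.625 to 1.67). In 17q21.2, with the type I keratins, LSD1 reached 3.81 times (2.67 to 5.28), KLF4 2.43 times (1.71 to 3.35), RCOR1 2.39 times (1.61 to 3.41) and ZNF750 1.52 times (1.01 to 2.2). Among bands of the same stain, LSD1 stood above 98.7%, KLF4 above 90.8%, RCOR1 above 78.9% and ZNF750 above 67.1%. In 18q12.1, with the desmosomal cadherins, ZNF750 was at 0.653 times (0.46 to 0.9), KLF4 at 0.618 (0.414 to 0.888), LSD1 at 0.413 (0.213 to 0.721) and RCOR1 at 0.284 (0.142 to 0.509). This is a band of the darkest stain, where all lists are sparse, and among the 75 such bands it was ordinary, above 49.3% of them for ZNF750, 66.7% for KLF4, 34.7% for LSD1 and 30.7% for RCOR1. Band 3q28, with TP63, was at 1.64 times for ZNF750 (1.23 to 2.14), 1.19 times for KLF4 (0.816 to 1.69), 1.09 times for RCOR1 (0.696 to 1.62) and 0.903 times for LSD1 (0.505 to 1.49). It is a band of dark stain, and among the 84 such bands it stood above 98.8% for ZNF750, 92.9% for KLF4, 79.8% for RCOR1 and 61.9% for LSD1. Of its 53 ZNF750 peaks over 4.4 Mb, 29 lay in the 1 Mb window already picked for its many ZNF750 peaks. The ZNF750 density of 3q28 therefore largely restates that window and is no separate support for it.

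Bands that textbooks give for the genes of the studied proteins were looked up as well. In 17q25.3, with ZNF750 itself, LSD1 stood at 2.92 times, KLF4 at 2.28, RCOR1 at 1.92 and ZNF750 at 1.7 times the autosomal density. This was above 97.3% of bands of the same stain for LSD1, 94.0% for KLF4, 83.9% for RCOR1 and 86.6% for ZNF750. In 1p36.12, with KDM1A, RCOR1 reached 3.81 times (2.95 to 4.84) with 67 peaks, LSD1 2.19 times (1.47 to 3.15), KLF4 1.74 times (1.22 to 2.39) and ZNF750 1.4 times (0.978 to 1.93). Against bands of the same stain, RCOR1 stood above 96.1%, LSD1 above 84.2%, KLF4 above 61.8% and ZNF750 above 63.2%. In 14q32.31, with RCOR1, KLF4 stood at 1.82 times (1.11 to 2.82) and ZNF750 at 1.21 times (0.69 to 1.96), and the intervals of the other 2 lists also included 1. KLF4 density there was above 80.9% of bands of the same stain. In 9q31.2, with KLF4, the intervals of all 4 lists included 1, with ZNF750 at 1.27 times (0.851 to 1.82).

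**Figure D5:**
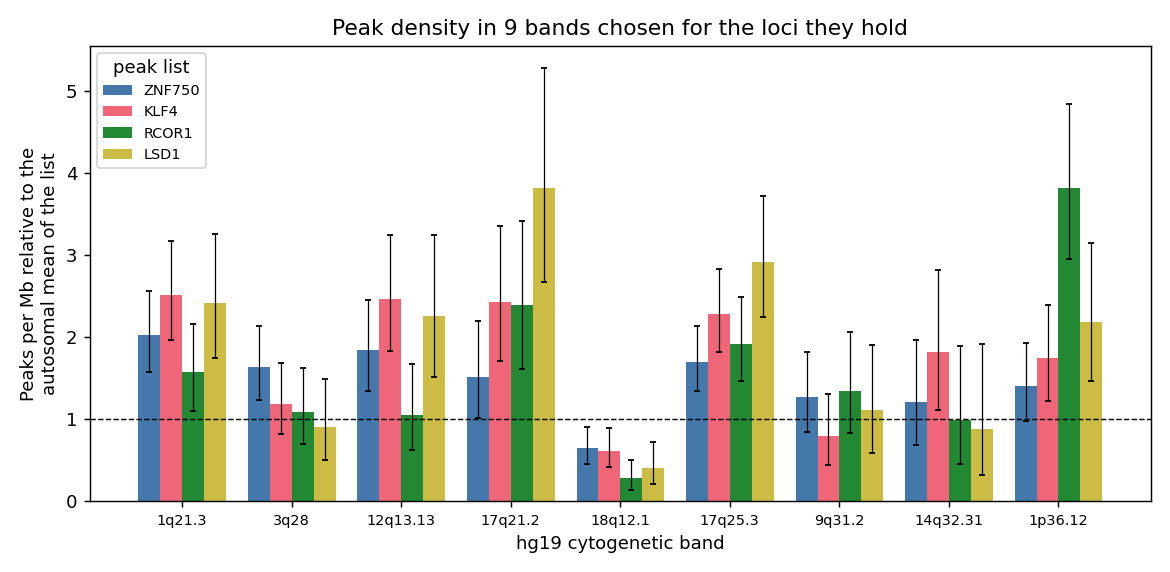
Peaks per Mb in 9 hg19 cytogenetic bands, relative to the autosomal mean of the same list (y axis, dashed line at 1), with exact Poisson 95% intervals as error bars that cover counting error only. Band 1q21.3 reaches 2.02 for ZNF750, 17q21.2 reaches 3.81 for LSD1, and 18q12.1 lies below 1 for all 4 lists.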

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

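The settings that use a local shift, leave out centromere-near and repeat-like peaks, keep autosomes only, stratify by score and width or rank by width were chosen after the data were seen. For all 6 pairs the observed sharing stayed above every shift under each of the 8 alternatives, RCOR1 with LSD1 had the highest ratio and ZNF750 with RCOR1 the lowest in each, and the lowest ratio ranged from 7.56 (local shift) to 45.1 (midpoints within 200 bp). Ratios rose with stricter overlap, where shifted counts fell more than observed ones. The share of ZNF750 peaks with all 3 partners, 3.62%, was 2.54% with a reciprocal overlap of 50%, 2.47% with midpoints within 200 bp, 2.43% among the upper 50% of each list by score and 3.33% without centromere-near and repeat-like peaks. These settings remove overlaps or peaks by construction. The difference in share between RCOR1 and LSD1 at ZNF750 peaks (RCOR1 minus LSD1, -1.87 percentage points) was -0.31 with reciprocal overlap (adjusted exact McNemar p = 0.1941) and turned to 0.56 among the upper 50% by score (adjusted exact p = 0.0936), and the cause was not tested. The other 114 comparisons with an alternative kept direction and side of the threshold or, where no test applied, stayed within the interval. So did 4 of the added comparison at RCOR1 peaks. Not all of the 114 were designed in advance, since they include the McNemar and quintile tests, which were added after the data were seen. Some rises with score became much smaller all the same. With a reciprocal overlap of 50%, the rise from the lowest to the highest quintile of ZNF750 score fell from 19.1 to 10.4 percentage points for KLF4 and from 14.3 to 8.05 for LSD1, and that of RCOR1 peaks shared with KLF4 from 27.7 to 17.4. With quintiles of width in place of score, the rise of LSD1 peaks shared with RCOR1 fell from 13.8 to 3.99 points, that of ZNF750 peaks shared with RCOR1 from 11.9 to 6.13, and those of KLF4 peaks shared with RCOR1 and with LSD1 from 9.75 to 4.66 and from 13.7 to 8.12. KLF4 peaks were shared with ZNF750 at 21.7% in the lowest and 34.4% in the highest width quintile, against 19.1% and 40.3% by score. Other rises were larger by width than by score. Those of RCOR1 peaks went from 22.7 to 26.1 points with ZNF750 and from 27.7 to 30.7 with KLF4. Those of LSD1 peaks went from 13.4 to 16.0 with ZNF750 and from 15.3 to 17.1 with KLF4. A rise with score was examined within quintiles of width only for RCOR1 peaks shared with LSD1. With 1 list per antibody no replicate could be left out, and the unknown read depth limits what the lengths of the lists show. The alternatives planned for distances to genes, gene lists, differentiation against progenitor genes and motifs were not run, since no hg19 annotation or sequence was used here.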

Other observations

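All tests in this part were added after overlap counts had been seen: those on G-band stain, the local shift, the count of shared peaks near centromeres, the strata of score and width, and those on the width and the weak end of the RCOR1 peaks. Over all autosomes, the ZNF750 list reached further into dark G-bands, which hold fewer genes, than the lists of its partners did. It had 9.08 peaks per Mb in unstained bands and 5.25 in the darkest, a ratio of 1.73, against 2.61 for KLF4, 2.79 for RCOR1 and 2.4 for LSD1. The 2 darkest stain classes held 23.89% of ZNF750 peaks, against 18.27% of KLF4, 17.59% of RCOR1 and 19.4% of LSD1 peaks (Fisher's exact test, largest adjusted p = 3.47e-20). Among ZNF750 peaks, 25.34% of those with no partner lay in these classes, against 19.18% of those with KLF4 alone (Fisher's exact test, adjusted p = 3.41e-13) and 20.55% of those with KLF4 and a chromatin regulator (adjusted p = 5.08e-06, exact). For those with RCOR1 or LSD1 without KLF4 the share was 24.54% (adjusted p = 0.4341, exact). These shares were not compared at equal list lengths or within strata of score. The ZNF750 list was the longest, and its peaks with no partner had lower scores (median 159.2) than those with KLF4 alone (210.9). List length and peak score may therefore contribute to these differences.

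The 6 pairs of lists shared far more peaks than shifted lists did. Regions dense in peaks of every list, on a scale above 50 kb, were excluded as the whole cause, since moving peaks by 10 to 50 kb left a ratio of at least 7.56. Peaks in or within 1 Mb of centromere, variable or stalk bands were too few to be the whole cause. The ZNF750, KLF4, RCOR1 and LSD1 lists held 415, 403, 250 and 239 of them, against at least 2616 shared peaks per pair. They made up at most 4.43% of the shared peaks of a pair. Together with repeat-like peaks they were 1.7% to 2.24% of each list, so they were somewhat more frequent among shared peaks. Without them the ratios lay between 11.7 and 39.5. The sites on chromosome 21 p11.2 and chromosome 1 p22.2, near the top of all lists, may be artifacts of mapping, and they are the only 2 ZNF750 peaks with scores in the top 1% that overlap such a peak in each of the other 3 lists. Open chromatin that any antibody recovers cannot be told apart from joint binding, since 0 lists of an input or an unrelated antibody were analysed (sites that any antibody recovers).

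KLF4 and the chromatin regulators met at ZNF750 peaks more often than independence gives. ZNF750 peaks of high score or width were shared more often, but within 25 strata of score and width the lower bound of the smaller odds ratio was still 2.96, so these traits were excluded as the whole cause. The lists come from populations of cells, so sites where KLF4 and RCOR1 or LSD1 overlap may be bound by both at once or by each in different cells. That was not tested. Open chromatin that any antibody recovers could also bring these overlaps to the same ZNF750 peaks. Without a list of an input or an unrelated antibody, it cannot be told apart from joint binding here either.

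RCOR1 peaks were shared with LSD1 at 4.59% in the lowest and 63.49% in the highest RCOR1 quintile. Peak width was excluded as the whole cause, since within each width quintile the highest score quintile was shared at least 2.87 times as often as the lowest. A weak end of the RCOR1 list that other antibodies seldom recover is a candidate explanation: the shares with ZNF750 and KLF4 fell too from the highest to the lowest quintile, by factors of 4.3 and 5.63. The share with LSD1 fell by a larger factor, 13.8, so such a weak end may cover only part of the pattern. Shares fell with score in the other lists too, less steeply, by factors of 2.25 to 2.69 for ZNF750 peaks. The falls with ZNF750 and KLF4 alone therefore cannot establish a weak end particular to RCOR1. The lowest RCOR1 quintile still met LSD1 peaks 7.95, KLF4 peaks 6.35 and ZNF750 peaks 5.25 times as often as after shifts along whole chromosomes. The local shift raised the chance level for the full lists, and no ratio against it is given for this quintile. The LSD1 list is a subset of a longer list, so RCOR1 peaks without overlap may still meet LSD1 peaks left out of it. Whether such omitted LSD1 peaks contribute to the fall with RCOR1 score was not tested. Sites where RCOR1 acts without LSD1 remain an untested alternative for part of the lowest RCOR1 quintile.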
